A study of Homo sapiens with 27 samples.

How the data were processed

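Total RNA of H9 cells and their derivatives was sequenced in 27 libraries of 8 groups. Per the labels' protocols, ES cells were grown on Matrigel in mTeSR1, neural progenitors (hNPC) were harvested at day 7 of neural induction, and neurons at day 22 of a STEMdiff protocol through embryoid bodies. Cortical organoids were made from embryoid bodies with Dorsomorphin, the WNT inhibitor IWR1, the TGF-beta inhibitor SB431542 and cyclopamine and taken at day 45. Libraries were made with the TruSeq Stranded Total RNA kit and read as paired ends of 100 cycles.

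The authors made the counts: by the submitters' processing notes, CASAVA was used for base calls, reads were placed on hg19 and HTSeq 0.6.1p1 counted reads per gene. The deposited tables hold raw read counts per gene symbol, for 1 library each outside the organoids. The organoid libraries are columns of 1 shared table. The aligner and the gene annotation are not given in the sources used here. All 27 libraries were counted over the same 28930 gene symbols, and no sample column was left unused. The annotation at hand was of another genome build, so no coordinates were used.

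Of the total in each table outside the organoids, named genes held 39.6 to 65.1% and reads over no feature 30.8 to 55.4%. The organoid table has no rows for reads outside named genes, so these shares are not known there. Gene counts per library came to 33.6M to 41.4M in ES cell 53BP1 KO, 25.0M to 32.0M in ES cell control, 23.7M to 28.7M in UTX KD, 26.5M to 31.9M in hNPC, 29.7M to 36.8M in neuron 53BP1 KO, 24.4M to 30.1M in neuron control, 3.15M to 17.5M in organoid 53BP1 KO and 12.3M to 20.9M in organoid control. At a depth of 25M a gene at 1 CPM has about 25 counts, and in the shallowest organoid library about 3. The mitochondrial transcripts had 0 counts throughout, so that list was not tested.

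Groups followed the labels: genotype, cell stage, clone and replicate number. The number of a UTX KD library may be a construct or a replicate, as the labels do not say. Libraries of a group were compared pair by pair for shared origin. The lowest median chi-square per gene between replicates was 0.987 (hNPC) and the lowest mean 5.12, so no library was a copy of another.

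Each comparison was tested with edgeR 4.0.16 (quasi-likelihood F-test, glmQLFit with robust=TRUE) in R 4.3.3, over only the libraries of its groups. Counts were scaled by TMM, genes kept by filterByExpr (minimum count 10, minimum total 15), and p-values adjusted by Benjamini-Hochberg over the genes tested, with a call at FDR under 0.05. The comparisons were 53BP1 KO and UTX KD against control in ES cells, hNPC against ES cell control, and 53BP1 KO against control in neurons and in organoids. Contrasts of effects compared UTX KD with 53BP1 KO in ES cells, 53BP1 KO in neurons with that in ES cells, and 53BP1 KO in organoids with that in neurons, each in 1 fit over all groups involved. The tests, groups, gene lists and rule for named genes were chosen before the data were examined.

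Named genes came by rule. TP53BP1 and KDM6A were read in every library first. For each comparison the 6 largest rises and 6 largest falls followed among genes with FDR under 0.05, a mean of at least 1 CPM and no overlap of CPM between the groups, without clone-type, noncoding, pseudogene and antisense symbols. Of each list described, up to 4 members with the smallest p were named, and of each overlap or contrast of effects 6 genes with the smallest p under the same skips. Symbols that end in P and digits were skipped as pseudogenes, which also left out coding genes such as IGFBP3, the gene with the smallest p between organoids and neurons. POU5F1, NANOG, SOX1, DCX, COL3A1 and TTR were also read per library, a choice made after values were seen. Where a group had 1 to 3 counts in all, the ratio of summed counts over depth is given with a 95% interval, and where it had 0, a bound with 3 counts over the group as the floor.

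Gene lists (27 fixed, 26 tested) were tested with limma 3.58.1 camera with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, on voom values, adjusted over the lists of a comparison. Members were counted over all genes tested and adjusted over the list alone. Genes of neural induction were those called in hNPC with an absolute log2 fold change of at least 2, and sets of the 200 genes with the smallest p per direction were a smaller alternative. Overlaps of calls were set against independent lists of the same sizes and, for the ES cell comparisons that share controls, against 20 simulated pairs of unchanged groups and against controls split in disjoint parts.

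The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, calls with an absolute log2 fold change of at least 1, leaving out each library in turn, the replicate number as a block, all ES cell and hNPC libraries in 1 fit, and libraries of a clone summed. Added after the data were seen were each UTX KD library alone, the organoid libraries split by or adjusted for their counts over olfactory receptor genes, disjoint controls, fry on the neural induction genes, leaving out each library and calls of at least 2-fold in the contrasts of effects, and the sets of 200 genes with an estimated correlation. A count was taken as moved when it changed more than 1.5-fold. Leaving out a library so that 1 remains in a group assumes that the spread of the other group holds for both.

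The procedure was tested on simulated data: in counts of each comparison's libraries 200 genes were changed 2-fold or 4-fold (100 each). Recovered were 62 and 95% in ES cell 53BP1 KO, 22 and 70% in UTX KD, 68 and 95% in hNPC, 11 and 81% in neurons and 7 and 54% in organoids. Most 2-fold changes in UTX KD, neurons and organoids were thus missed when only 200 genes changed. The adjustment is less strict where more genes change, so these shares do not carry over to the real comparisons. There 3413 of 4635 calls in neurons and 1205 of 2608 in UTX KD were at least 2-fold, and the others were smaller. In the simulated data unchanged genes made up 8.19% of the calls for ES cell 53BP1 KO and 2.13% for UTX KD. The share was 5.23% for hNPC, 8.0% for neurons and 8.96% for organoids. Such a share is not known for the real calls. Values far from the rest of their group were found with Dixon's test at the 0.95 level. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.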

Results

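H9 is a human embryonic stem (ES) cell line. The series asks how UTX, the histone demethylase encoded by KDM6A, and 53BP1, the DNA double-strand break protein encoded by TP53BP1, act on the genes of neural differentiation. RNA was counted over 28930 gene symbols in 27 libraries of 8 groups: ES cells (5 control, 3 labelled 53BP1 KO, 3 labelled UTX KD), neural progenitors (hNPC, 3 control), day 22 neurons (2 control, 3 labelled 53BP1 KO from 2 clones) and day 45 cortical organoids (2 control, 6 labelled 53BP1 KO from 3 clones). Gene counts came to between 23.7M and 41.4M per library in the ES cell, hNPC and neuron groups. The organoid libraries were shallower, with 3.15M to 17.5M in the KO group and 12.3M and 20.9M in the controls. Values are normalized CPM (read counts relative to the library total), given as mean ± SD over libraries unless plain CPM is named, and adjusted p is the false discovery rate over all genes of a comparison. The p-values measure the spread between libraries, which may be technical, since the labels do not say whether libraries of a group came from separate cultures.

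TP53BP1 was at 143, 151 and 321 plain CPM in ES cell 53BP1 KO clones 1, 2 and 3, against 258 to 367 in the 5 controls, so that the library labelled clone 3 lay within the range of the controls. As normalized CPM the group stood at 208 ± 100 (n = 3) against 317 ± 37.1 (n = 5), a difference not past the test (adjusted p = 0.15). In day 22 neurons TP53BP1 was 3.76-fold lower in the KO libraries, at 117 ± 19.4 (n = 3) against 442 ± 23.6 (n = 2, adjusted p = 0.013). The organoid KO libraries had 123 ± 21.5 (n = 6) against 160 ± 13.5 (n = 2), not past the test (adjusted p = 0.649). As plain CPM the library labelled clone 1 replicate 2 had 144, within the controls' 142 to 163. A knockout need not lower the transcript of its target, so these levels check the labels only in part. KDM6A was at 31.7, 135 and 71.7 plain CPM in UTX KD 1, 2 and 3, against 128 to 162 in the 5 controls, so that the library labelled UTX KD 2 again lay among the controls (group adjusted p = 0.271). KDM6A fell 2.85-fold from ES cells to hNPC, from 147 ± 8.67 (n = 5) to 51.5 ± 1.19 (n = 3, adjusted p = 1.7e-07), and was 1.51-fold higher in KO than in control neurons (94.5 ± 2.21 against 62.5 ± 0.202, adjusted p = 0.0333).

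**Figure D1:**
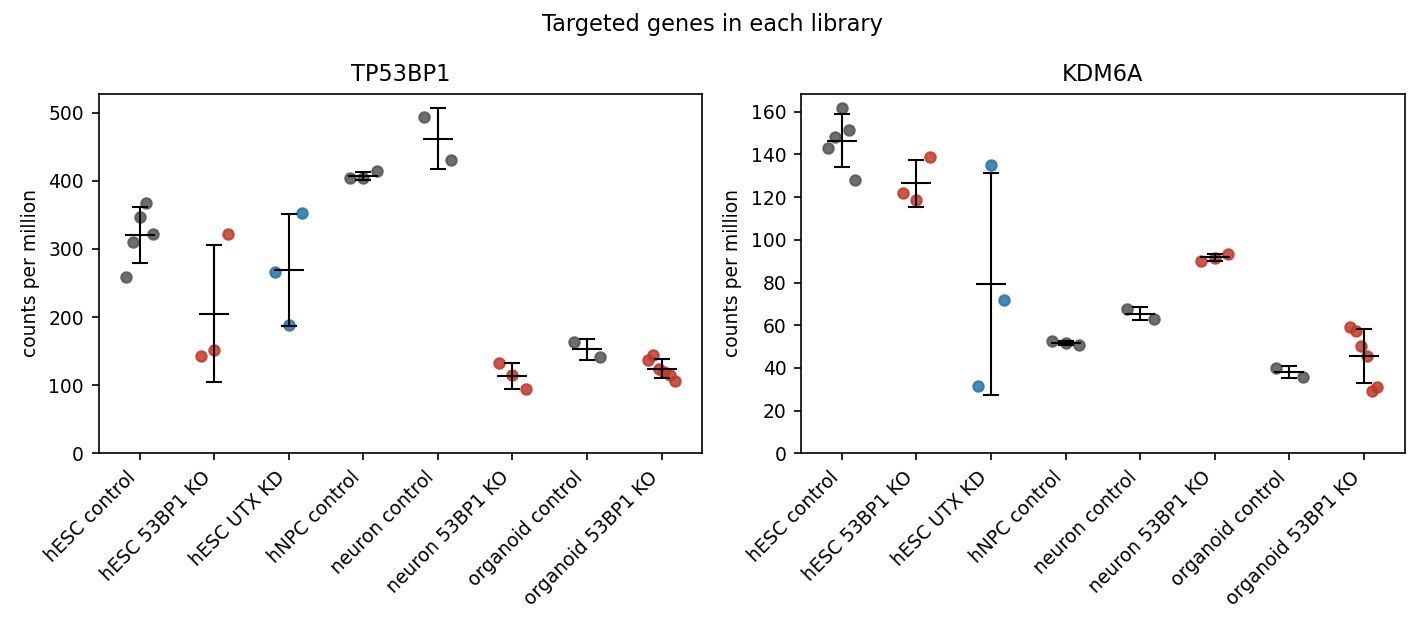
Plain CPM of TP53BP1 and KDM6A in each of the 27 libraries (points), with the mean and SD of each group (black). Red marks 53BP1 KO, blue UTX KD and grey control libraries.

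Control ES cells and control hNPC (n = 5 and 3) were compared to place the genes of neural induction. Pluripotency genes fell: POU5F1, which encodes OCT4, had 1 count over the 3 hNPC libraries against 113074 over the ES cells (831 ± 123 CPM; count ratio 72311, 95% interval 12978 to 2856200). The Nodal co-receptor gene TDGF1 went from 558 ± 69.8 CPM to 0 counts, at least 16120-fold lower. L1TD1, a pluripotency RNA-binding protein, fell 5022-fold (0.232 ± 0.0768 against 1183 ± 165, adjusted p = 1.69e-09) and LIN28A 81.8-fold (22.7 ± 2.44 against 1856 ± 250, adjusted p = 3.74e-09). All 19 tested members of the pluripotency list fell (19 adjusted over the list alone, camera adjusted p = 5.4e-08, adjusted p = 0.194 with an estimated correlation). Epithelial genes fell with them, 11 of 12 over all genes (11 adjusted over the list alone, camera adjusted p = 5.59e-05, adjusted p = 0.102 with an estimated correlation). Among them were EPCAM, from 189 ± 22.7 to 1.98 ± 0.259, and the keratins KRT8 and KRT18.

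Several patterning genes came up from 3 counts or fewer over the ES cell group in hNPC. OTP, a hypothalamic transcription factor gene, reached 62 ± 10.7 CPM (5388 against 1 counts; ratio 8425, interval 1512 to 332840), and the signalling gene WNT7A 79.5 ± 7.6 (6906 against 3 counts; ratio 3600, interval 1231 to 17459). The hindbrain and spinal cord genes HOXA2, HOXB2 and HOXB3 reached 33.6 ± 1.04, 30.7 ± 2.02 and 46.2 ± 0.576 CPM, and HOXB4 and HOXB9, without a count in ES cells, were at least 394-fold and 1022-fold higher. Of the midbrain and hindbrain list 17 of 21 members rose and none fell (18 adjusted over the list alone, camera adjusted p = 4.94e-07, adjusted p = 0.263 with an estimated correlation). The forebrain list split into 6 rises and 6 falls of 12 (6 and 6 adjusted over the list alone, camera adjusted p = 0.954). FOXG1, the telencephalic factor gene, rose 37.8-fold but only to 18.8 ± 1.88 CPM (adjusted p = 3.04e-05). Intervals on count ratios cover counting error only, here and wherever a ratio is given.

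Neural and neuronal genes made up the other large rise in hNPC. The neural progenitor list had 19 rises and 4 falls among 24 (19 and 4 adjusted over the list alone, camera adjusted p = 5.59e-05, adjusted p = 0.322 with an estimated correlation). It was led by the homeobox gene MEIS2 (801-fold, to 389 ± 23.8 CPM, adjusted p = 2.88e-08) and the radial glia gene FABP7 (453 ± 25.7 against 13.9 ± 3.49). Of 22 neurogenic transcription factor genes 19 rose and none fell (19 adjusted over the list alone, camera adjusted p = 2.83e-07, adjusted p = 0.373 with an estimated correlation). They included LHX1, 117-fold (adjusted p = 3.67e-09), EBF2, EBF3 and NHLH1. DCX, the microtubule protein of young neurons, rose 102-fold to 869 ± 112 CPM (adjusted p = 1.48e-09). The pan-neuronal list had 23 rises and 3 falls among 28 (23 and 3 adjusted over the list alone, camera adjusted p = 1.16e-06, adjusted p = 0.194 with an estimated correlation). In the axon guidance list 22 of 28 rose and 4 fell (22 and 4 adjusted over the list alone, camera adjusted p = 0.000257, adjusted p = 0.434 with an estimated correlation). SLIT1 was at 335 ± 27 against 3.01 ± 1.21 CPM and UNC5D 12.1-fold lower. Notch pathway genes rose in 14 of 18 cases and fell in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.322 with an estimated correlation).

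Repair and translation genes also moved between ES cells and hNPC, whereas chromatin genes did not pass as a list. The H3K27 and H3K4 methylation list had 6 rises and 7 falls of 21 (6 and 7 adjusted over the list alone, camera adjusted p = 0.748). The Polycomb genes EZH2 and EZH1 were 1.78-fold and 1.74-fold higher in hNPC, whereas JARID2, a Polycomb cofactor gene of ES cells, fell 3.61-fold, to 141 ± 3.47 from 508 ± 68.4 CPM (adjusted p = 6.1e-07). Double-strand break genes fell in 18 of 24 cases and rose in 5 (18 and 5 adjusted over the list alone, camera adjusted p = 0.00342, adjusted p = 0.194 with an estimated correlation). BRCA2, NBN, RNF168 and USP28 fell 1.70-fold to 2.25-fold, while TP53BP1 rose, by 0.34 on the log2 scale (406 ± 4 against 321 ± 36.2, adjusted p = 0.0113). Ribosomal protein genes fell in 24 of 26 cases (24 adjusted over the list alone, camera adjusted p = 4.63e-06, adjusted p = 0.586 with an estimated correlation). Replication-dependent histone genes rose in 13 of 19 cases and fell in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0384, adjusted p = 0.767 with an estimated correlation). That call left the threshold without ES cell control 1 (0.0716), 2 (0.0557) or 3 (0.0567) or without hNPC 1 (0.0503). In all, 12265 of 17296 tested genes were called by edgeR, 5963 higher and 6302 lower in hNPC, and 7143 of them at least 2-fold. No single library moved that count past a range of 11043 to 12844.

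In ES cells labelled 53BP1 KO (n = 3 against 5 controls) the largest rises among the genes named by rule were in CTSG, SRGN, LYZ, POSTN, BCHE and ANGPT1. CTSG, which encodes cathepsin G, had 380 counts over the KO libraries against 1 over the controls (3.41 ± 0.592 CPM; count ratio 467, interval 83.2 to 18477, adjusted p = 0.000235). Serglycin (SRGN) rose 48.1-fold to 3.38 ± 0.303 CPM (adjusted p = 0.00276) and lysozyme (LYZ) from 0.166 ± 0.112 to 5.12 ± 0.464 (adjusted p = 0.00199). Periostin (POSTN), the cholinesterase BCHE and the angiopoietin ANGPT1 rose 2.82-fold to 3.07-fold, to between 4.9 and 13.1 CPM. Mesenchyme and matrix genes rose in 5 of 15 cases and fell in none (5 adjusted over the list alone, camera adjusted p = 0.0579). COL1A2 went from 163 ± 38.6 to 297 ± 32.7 and FBN1 from 40.6 ± 6.82 to 70.4 ± 14.4. The axon guidance genes SEMA3A (1.89-fold; 185 ± 5.81 against 98 ± 12.5, adjusted p = 0.00315), SEMA3D and UNC5D rose too, 3 of 28 in their list (3 adjusted over the list alone, camera adjusted p = 0.13).

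Genes lower in the ES cells labelled 53BP1 KO included the histone methyltransferases that act with UTX. KMT2D fell 2.18-fold, from 271 ± 60.2 to 124 ± 24.1 CPM (adjusted p = 0.00721), and KMT2C 1.6-fold, from 201 ± 34.9 to 126 ± 19.3 (adjusted p = 0.0199). With SUZ12 and ASH2L they made 4 falls and no rise among 21 genes of the H3K27 and H3K4 methylation complexes (4 adjusted over the list alone, camera adjusted p = 0.13). Pluripotency genes shifted little: SALL4 fell 1.42-fold (280 ± 7.51 against 397 ± 46, adjusted p = 0.0196), UTF1 fell and LEFTY1 rose, 2 falls and 1 rise among 19 (3 and 1 adjusted over the list alone, camera adjusted p = 0.424). The largest falls, HIST1H4F (237-fold), HIST1H4L (81-fold), CTSF (61.7-fold), MLKL (26.5-fold), GDA (24.8-fold) and C5orf63 (18-fold), were in genes whose controls ranged widely, such as CTSF at 13.9 ± 18.5 CPM. Histone genes exist as near-identical copies, so the assignment of reads to HIST1H4F, HIST1H4L and other copies is uncertain. The unfolded protein response genes PDIA4, HSPA5, HSP90B1 and XBP1 rose 1.5-fold to 1.87-fold, in a list with 4 rises and 1 fall of 19 (4 and 1 adjusted over the list alone, camera adjusted p = 0.469). The median and mean of that list differed in sign (log2 -0.05 and 0.06).

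edgeR called 1935 of 16828 genes in this comparison, 1116 higher and 819 lower, and 227 of them at least 2-fold. None of the 26 lists tested passed camera (lowest adjusted p 0.0579). The count was 391 without KO clone 1, 1169 without clone 2, 1008 without the library labelled clone 3, whose TP53BP1 was not lowered, 3112 without control 1, 1290 without control 3 and 1139 without control 4. DESeq2 called 3050.

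The 3 ES cell libraries labelled UTX KD differed from one another along neural induction. In UTX KD 1, 2 and 3 POU5F1 was at 11.3, 1648 and 1258 plain CPM against 672 to 952 in the controls, and SOX1, a neural plate gene, at 105, 0.777 and 19.4 against 0.0625 to 2.24. Over the 1591 genes higher in hNPC by at least 2 on the log2 scale, the median log2 difference from the control mean was 1.22, -0.13 and 0.12, against 2.13 to 2.19 in hNPC and -0.10 to 0.09 in the controls. For the 2182 genes lower in hNPC it was -1.55, -0.31 and -0.78, against -1.96 to -1.95 in hNPC. The same ES cell controls define these genes and the zero of the scale.

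**Figure D2:**
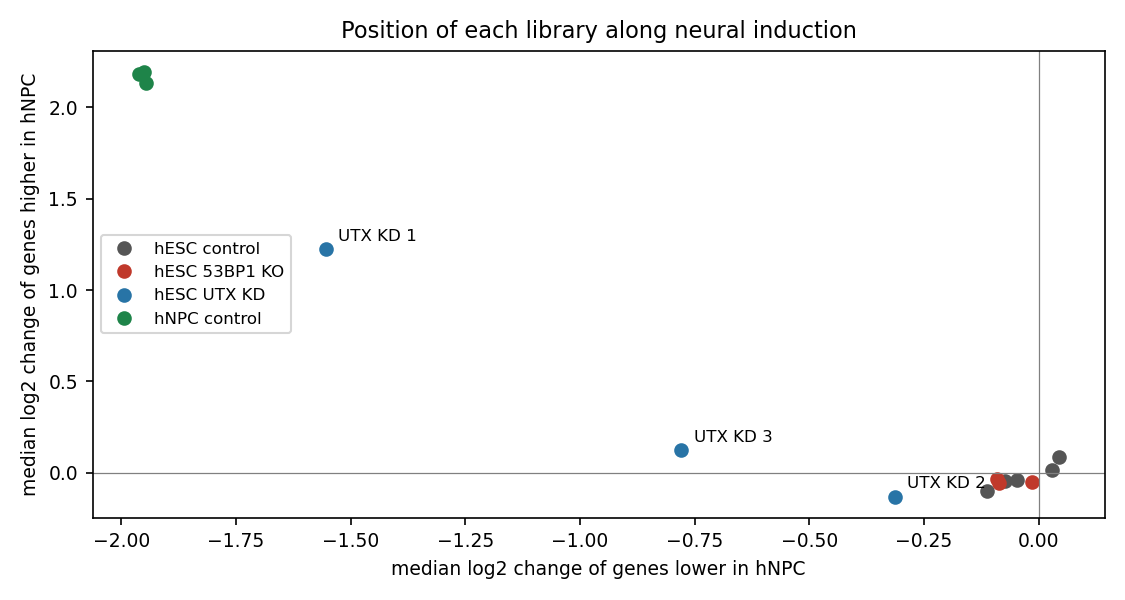
Median log2 difference from the mean of ES cell controls, per library, of the 2182 genes lower in hNPC (x axis) and the 1591 genes higher in hNPC (y axis). Each point is 1 library.

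The largest rise in UTX KD (n = 3 against 5) among the genes named by rule was in COL3A1. This collagen gene was at 1377, 4.17 and 63.7 plain CPM in UTX KD 1, 2 and 3 against 0.0380 to 0.438 in the controls (2372-fold, adjusted p = 0.0097). A2M, the neurotrophin receptor NTRK2, the neural factor POU3F3, MEIS1 and the phosphodiesterase PDE1A rose 157-fold to 304-fold, and DCX 9.97-fold (80.2 ± 92.3 against 8.04 ± 0.799, adjusted p = 0.0168). The mesenchyme and matrix list had 3 rises and 3 falls of 16 (3 and 3 adjusted over the list alone, camera adjusted p = 0.519), with a median of -0.26 and a mean of 0.54 on the log2 scale. SOX1, MEIS2 and FABP7 rose while the forebrain gene OTX2 fell 4.66-fold, in a neural progenitor list with 7 rises and 1 fall of 24 (14 and 1 adjusted over the list alone, camera adjusted p = 0.0819). Neurogenic factors, with POU3F2, EBF1, EBF3 and MYT1L, rose in 6 of 16 cases (11 adjusted over the list alone, camera adjusted p = 0.0593). Pan-neuronal genes rose in 8 of 28 cases, with MAPT and NEFM, and fell in 1, the kinesin KIF5A, 2.07-fold (12 and 2 adjusted over the list alone, camera adjusted p = 0.667). EBF3 and EBF1 were not higher in UTX KD 2 taken alone (log2 -0.00398 and -1.01).

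Camera called histone, ribosomal and cell cycle lists higher in UTX KD with the preset correlation only. Replication-dependent histone genes rose in 17 of 19 cases (17 rises and 1 fall adjusted over the list alone, camera adjusted p = 3.1e-13, adjusted p = 0.939 with an estimated correlation). HIST1H4D rose 3.52-fold, from 156 ± 26.9 to 548 ± 48.2 CPM (adjusted p = 0.00206), with HIST1H4B, HIST1H4C and HIST1H2AB alongside. Ribosomal protein genes rose in 8 of 26 cases (21 adjusted over the list alone, camera adjusted p = 2.89e-07, adjusted p = 0.939 with an estimated correlation). RPL10 rose 2.07-fold (862 ± 111 against 416 ± 58.5, adjusted p = 0.0075), with RPLP0, RPS14 and RPS19. Cell cycle genes rose in 12 of 24 cases (12 adjusted over the list alone, camera adjusted p = 1.02e-05, adjusted p = 0.939 with an estimated correlation). Among them were the thymidylate synthase gene TYMS 2.36-fold (77.4 ± 17.5 against 32.9 ± 2.62, adjusted p = 0.00509), PCNA 1.8-fold, CCNA2 1.6-fold and BIRC5 1.74-fold. The UTX KD libraries also differed in makeup. The signal recognition particle RNA RN7SL1 took 7.78 to 8.42% of their gene counts against 2.16 to 2.80% in the controls. Alignments that were not unique took 7.0 to 20.5% of the tabled total against 2.67 to 13.3%.

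Genes lower in UTX KD included SALL4, 1.98-fold (191 ± 60.1 against 378 ± 42.6, adjusted p = 0.0245), the only member of 19 to fall in the pluripotency list (1 adjusted over the list alone, camera adjusted p = 0.000648, adjusted p = 0.939 with an estimated correlation). The telomerase gene TERT was not past the test (11.7 ± 9.21 against 27.5 ± 1.3, adjusted p = 0.122). No epithelial gene of 11 was called (0 adjusted over the list alone), CDH1 at 85.2 ± 140 against 353 ± 58.4 (adjusted p = 0.33), although the list passed camera (adjusted p = 0.0036, adjusted p = 0.939 with an estimated correlation). Without UTX KD 1 neither list passed (0.334 and 0.165). The protocadherin PCDHB5 (12.4-fold; 1.15 ± 0.515 against 14.3 ± 5.27, adjusted p = 0.00572), the protease inhibitor SPINK5 (13.7-fold), FAM20A (39.4-fold), CTSF (58-fold), GDA (90.9-fold) and HIST1H4L (13-fold) fell most.

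edgeR called 2608 of 16628 genes in UTX KD, 1645 higher and 963 lower, and 1205 of them at least 2-fold. The other 21 lists had camera adjusted p from 0.0593 to 0.972. The count was 5317 without the library labelled UTX KD 2, whose KDM6A was not lowered, 932 without UTX KD 3, and 901, 629, 689 and 1176 without control 2, 3, 4 and 5. Each KD library alone against the controls gave 7077, 911 and 2162 calls for UTX KD 1, 2 and 3, where the spread is that of the controls alone. DESeq2 called 4534.

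Set against each other, ES cells labelled UTX KD and 53BP1 KO differed in 4286 of 16961 genes, 2400 higher in UTX KD and 1886 lower. Of the 6 genes named by the smallest p, the plectin gene PLEC was lower in UTX KD and not in KO (log2 -1.68 and 0.21; difference -1.93), as was the kinesin KIF1A (-1.69 and 0.23; difference -1.95). EMC1, of the endoplasmic reticulum membrane complex, and FAM73B, a mitochondrial protein gene, moved in opposite directions (log2 -0.62 and 0.83, and -0.71 and 0.84). The histone copies HIST1H4J and HIST1H4D were higher in UTX KD only (differences 2.15 and 2.14). All 6 had adjusted p = 0.000176. The count was 1931 without KO clone 1, 1990 without the library labelled KO clone 3 and 6551 without the library labelled UTX KD 2.

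Genes called in the same direction in ES cell 53BP1 KO and UTX KD numbered 217 of 16484 tested in both, 78 higher and 139 lower, and 139 more were called in opposite directions. The splicing factor gene SRRM2 (log2 -1.37 in KO and -1.53 in UTX KD), the adaptor CMIP (-0.96 and -1.26), the ubiquitin ligase HUWE1 (-0.70 and -0.85), and the chromatin remodelling genes ARID1A (-1.02 and -0.87) and BAZ2A (-0.67 and -0.92) fell in both, and CH17-373J23.1 rose in both (1.17 and 1.56). Independent lists of these sizes would share 107.54 higher and 47.85 lower, so that only the shared falls exceeded that value. Without KO clone 2, 99 genes were shared against 99.57 for independent lists. At least 2-fold in both, 49 genes were shared, against 7.28 for independent lists. There both the shared rises (12 against 2.82) and the shared falls (37 against 4.46) exceeded it. The log2 changes had a correlation of 0.214 and a covariance of 0.110 across genes, which are not independent replicates. In 20 simulated pairs of unchanged groups set against the same controls the correlation was 0.386 and the covariance 0.0478 on average. Their overlap of 0 says nothing about the 217, since at most 1 gene was called in any simulated comparison. With the controls split so that none served both comparisons, the correlations were 0.0482 and 0.159. The overlap could only be 0 there, since in each arrangement edgeR called 0 genes in 1 of the comparisons (3219 at unadjusted p below 0.05 in 53BP1 KO and 1824 in UTX KD). The shared count was 49 without KO clone 1, 99 without clone 2, 437 without control 1, 75, 50, 47 and 106 without control 2, 3, 4 and 5, 443 without the library labelled UTX KD 2 and 73 without UTX KD 3. It was 560 with DESeq2.

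At day 22 of neuronal differentiation the 53BP1 KO libraries (n = 3, from 2 clones) had pluripotency transcripts well above the controls (n = 2). POU5F1 was at 753, 1073 and 876 plain CPM in clone 1 replicates 1 and 2 and clone 2, against 8.07 and 131, and NANOG at 46.5, 82.4 and 102 against 1.13 and 17.6. SALL4 was 8.17-fold higher (248 ± 69.2 against 30.4 ± 9.84, adjusted p = 0.013), and DPPA4, LIN28B and the DNA methyltransferase DNMT3B were 3.66-fold to 6.19-fold higher. Over the pluripotency list 12 of 19 genes rose and none fell (15 adjusted over the list alone, camera adjusted p = 3.34e-08, adjusted p = 0.361 with an estimated correlation). Epithelial genes rose in 8 of 11 cases (8 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.000283, adjusted p = 0.361 with an estimated correlation). GRHL2, an epithelial transcription factor gene, rose 29.5-fold (15.6 ± 4.69 against 0.533 ± 0.276, adjusted p = 0.013), the cadherin CDH1 33.9-fold (116 ± 62.7 against 3.46 ± 2.37, adjusted p = 0.0131), CLDN7 and KRT19.

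**Figure D3:**
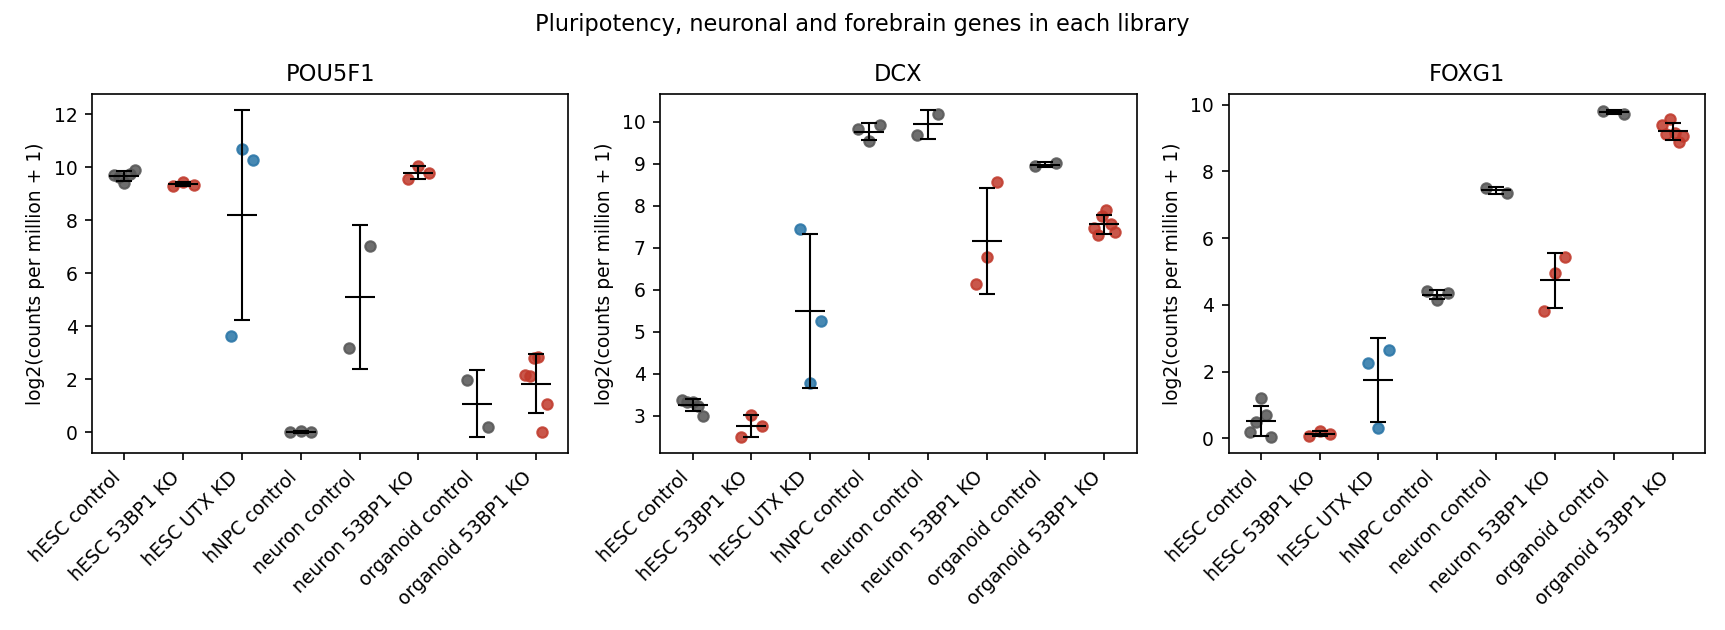
POU5F1, DCX and FOXG1 as log2 of plain CPM plus 1 in each of the 27 libraries (points), with the mean and SD of each group (black). Red marks 53BP1 KO, blue UTX KD and grey control libraries.

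Camera called the neuronal lists lower in the KO neurons with the preset correlation only. DCX was at 68.9, 109 and 380 plain CPM against 827 and 1160. Pan-neuronal genes fell in 17 of 28 cases and rose in 1 (23 and 1 adjusted over the list alone, camera adjusted p = 1.13e-08, adjusted p = 0.417 with an estimated correlation). ELAVL4 was 3.92-fold lower (26.4 ± 10.9 against 103 ± 1.8, adjusted p = 0.0134), L1CAM 3.75-fold (25.5 ± 8.55 against 95.7 ± 22.9, adjusted p = 0.0133), CRMP1 and KIF5A. Synapse and ion channel genes fell in 17 of 32 cases and rose in 1 (19 and 2 adjusted over the list alone, camera adjusted p = 1.45e-05, adjusted p = 0.361 with an estimated correlation). The neurexin NRXN1 fell 2.72-fold (52 ± 10.4 against 141 ± 3.14, adjusted p = 0.013), NRXN3 and the glutamate receptor GRIK2, while the scaffold gene HOMER1 rose 2.09-fold. Axon guidance genes fell in 14 of 28 cases and rose in 3 (17 and 4 adjusted over the list alone, camera adjusted p = 0.000565, adjusted p = 0.361 with an estimated correlation). NTN1, SLIT1 and EPHB2 were lower and SEMA6A 3.11-fold higher (278 ± 25.5 against 89.2 ± 18.2). Neurogenic factors fell in 10 of 24 cases and rose in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00448, adjusted p = 0.476 with an estimated correlation). EBF1 fell 5.99-fold (4.76 ± 1.98 against 28.5 ± 9.81, adjusted p = 0.013), and INSM1, MYT1 and FEZF2 fell too.

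Camera called progenitor, forebrain, Notch and matrix lists lower in the KO neurons with the preset correlation only, with members on both sides. FOXG1 fell 5.62-fold, to 29.3 ± 15 from 165 ± 4.26 CPM (adjusted p = 0.0149), DLX6 12.7-fold and ARX 8.44-fold, and TCF7L2 rose 2.6-fold. The forebrain list had 9 falls and 1 rise of 19 (9 and 1 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.361 with an estimated correlation). The eye field and telencephalic gene SIX3 fell 4.25-fold (1.92 ± 0.508 against 8.16 ± 1.82, adjusted p = 0.0142), with SIX6, LHX2 and HES5. The progenitor list had 12 falls and 1 rise of 25 (12 and 1 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.361 with an estimated correlation). Notch pathway genes fell in 8 of 17 cases and rose in 1, with JAG1 and HEY1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00448, adjusted p = 0.361 with an estimated correlation). Matrix genes fell in 9 of 18 cases and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00218, adjusted p = 0.446 with an estimated correlation). The fibrillin FBN1 fell 6.59-fold (82.7 ± 26.4 against 544 ± 147, adjusted p = 0.013), with COL5A1 and COL1A2, and THY1 was 1.85-fold higher. The largest falls were in ZNF667 (3 against 310 counts; count ratio 177, interval 60 to 863), HIST1H4F (44.2-fold), the keratin KRT17 (35.4-fold), HIST1H4L (32.4-fold), ZNF229 (30.3-fold) and the complement gene CFI (27.6-fold).

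Camera called ribosomal, hypoxia, stress response, cell cycle, repair and mesoderm lists higher in the KO neurons with the preset correlation only. All but 1 of 26 ribosomal protein genes rose (26 adjusted over the list alone, camera adjusted p = 1.56e-11, adjusted p = 0.417 with an estimated correlation). RPS3 rose 2.37-fold (1233 ± 61.5 against 520 ± 87.1, adjusted p = 0.0141) and RPL8 2.15-fold. Hypoxia and glycolysis genes rose in 12 of 20 cases (13 rises and 1 fall adjusted over the list alone, camera adjusted p = 0.000353, adjusted p = 0.361 with an estimated correlation). The glucose transporter SLC2A3 rose 4.81-fold (728 ± 72 against 151 ± 44.6, adjusted p = 0.013), with ALDOC, ADM and BNIP3. Genes of the ATF4 and unfolded protein response list rose in 5 of 19 cases (7 adjusted over the list alone, camera adjusted p = 0.00392, adjusted p = 0.417 with an estimated correlation). CHAC1 rose 11.2-fold (41.3 ± 27.3 against 3.7 ± 1.01, adjusted p = 0.0257), with PSAT1, PHGDH and XBP1. Cell cycle genes rose in 7 of 24 cases, with BUB1 and MCM3 (7 adjusted over the list alone, camera adjusted p = 0.00144, adjusted p = 0.417 with an estimated correlation). Break repair genes rose in 8 of 24 cases with 1 fall, TP53BP1 itself (12 and 2 adjusted over the list alone, camera adjusted p = 0.000565, adjusted p = 0.361 with an estimated correlation), and CHEK2, USP28 and MAD2L2 rose 2.15-fold to 3.72-fold. Of 20 mesoderm and endoderm genes 1 rose, the VEGF receptor KDR, 4.74-fold (96.2 ± 12.8 against 20.3 ± 2.32, adjusted p = 0.013; 1 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.557 with an estimated correlation). The list did not pass without clone 2 (0.284) or control 1 (0.287). The largest rises were in genes low in the controls: TEX13B (at least 45.2-fold), MLXIPL (count ratio 159, interval 28.4 to 6320), KLK8 (ratio 140, interval 24.8 to 5536), RGL3 (ratio 134, interval 45.6 to 650), INHBE (120-fold, to 23.6 ± 20 CPM) and CUZD1 (101-fold, to 120 ± 128).

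**Figure D4:**
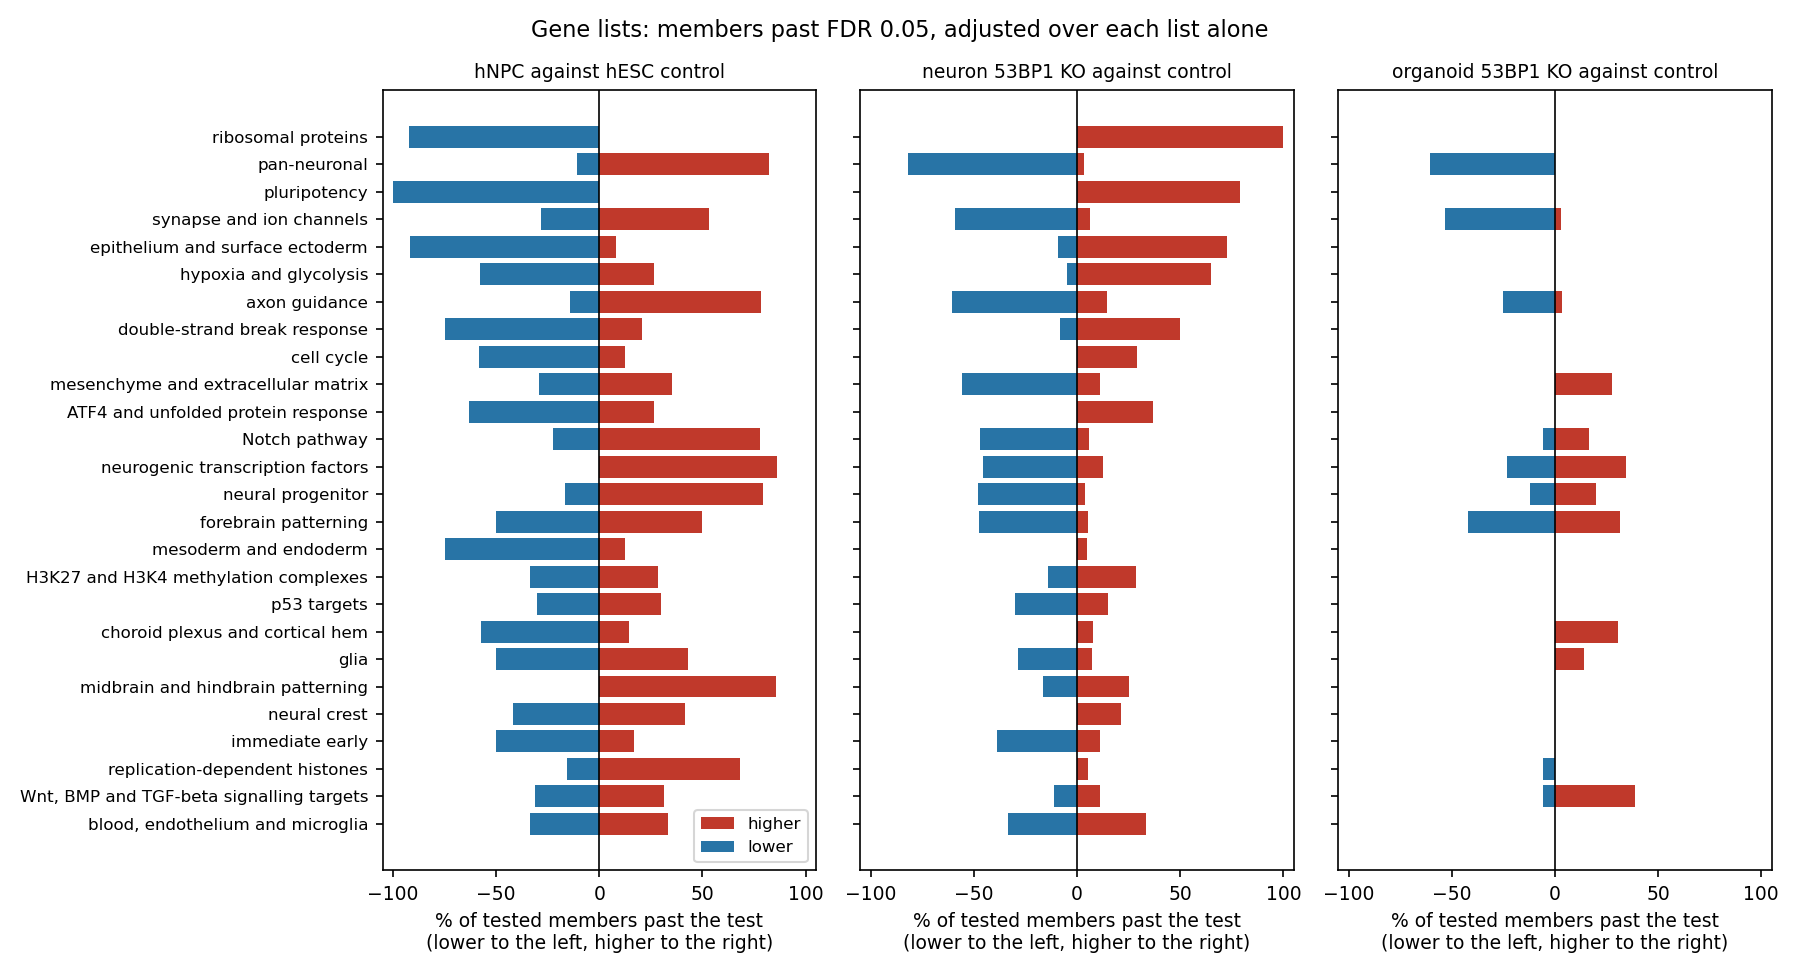
Percent of the tested members of each gene list past adjusted p 0.05, adjusted over the list alone, lower to the left (blue) and higher to the right (red). Panels show hNPC against ES cell control, day 22 neuron 53BP1 KO against control and day 45 organoid 53BP1 KO against control.

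edgeR called 4635 of 17320 genes in the neurons, 2457 higher and 2178 lower, and 3413 of them at least 2-fold. The other 10 lists had camera adjusted p from 0.14 to 0.894. The groups were small, and single libraries decided the count: edgeR called 0 genes without clone 1 replicate 2 (5386 at unadjusted p below 0.05), 0 without control 1 (4575), 2236 without clone 1 replicate 1, 7476 without clone 2 and 1252 without control 2. DESeq2 called 5937 genes over all libraries, and summing libraries of a clone gave 1535 with edgeR.

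Day 45 organoids labelled 53BP1 KO (n = 6, from 3 clones) were compared with 2 control libraries. The ventral progenitor gene GSX2 fell 18.2-fold, to 6.13 ± 3.53 from 107 ± 47.3 CPM (adjusted p = 0.0141), DLX1 10.0-fold, to 3.12 ± 1.76 from 30.1 ± 17.2 (adjusted p = 0.0428), and ASCL1 3.16-fold (57.3 ± 10.7 against 181 ± 32.3, adjusted p = 0.0185). The GABA synthesis gene GAD1 fell 6.01-fold (12.7 ± 3.44 against 76.2 ± 28.7, adjusted p = 0.00832) and the vesicular GABA transporter gene SLC32A1 8.79-fold (8.58 ± 3.27 against 74.7 ± 36, adjusted p = 0.0141). SIX3 fell 7.17-fold (5.77 ± 1.43 against 41.6 ± 7.88, adjusted p = 0.00484), and SLITRK6 (13.0-fold), the opioid precursor PDYN (18.3-fold), HIST1H3C (25.7-fold) and HIST1H2BB (14.4-fold) were the other largest falls. The dorsal cortical gene EMX2 rose 4.33-fold (59.8 ± 9.73 against 13.8 ± 3.13, adjusted p = 0.0106), as did ZIC2, 5.85-fold (130 ± 42.2 against 22.3 ± 6.51, adjusted p = 0.0400). Forebrain genes moved both ways, with 1 rise and 2 falls of 19 (6 and 8 adjusted over the list alone, camera adjusted p = 0.102).

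Camera called synapse, pan-neuronal and axon guidance lists lower in organoids labelled 53BP1 KO with the preset correlation only. The median log2 change over all tested genes was 0.16 (0.20 with RLE size factors), which list medians are to be set against. Synapse and ion channel genes had a median of -0.65, with 5 falls of 32 and no rise (17 and 1 adjusted over the list alone, camera adjusted p = 5.42e-14, adjusted p = 0.11 with an estimated correlation). Among them were NRXN3 (5.02-fold, adjusted p = 0.0421) and the sodium channel SCN3A (2.32-fold, adjusted p = 0.0428). Pan-neuronal genes had a median of -0.62, with 1 fall of 28, DCX, 2.82-fold (189 ± 43.1 against 533 ± 118, adjusted p = 0.0470; 17 falls adjusted over the list alone, camera adjusted p = 4.24e-11, adjusted p = 0.25 with an estimated correlation). Axon guidance genes had a median of -0.41 and 2 falls of 28, ROBO2 (2.85-fold; 96.9 ± 8.14 against 276 ± 108, adjusted p = 0.0226) and EPHB1 (2.06-fold; 7 falls and 1 rise adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.25 with an estimated correlation). ELAVL3, SCG3 and STMN4 were not past the test (adjusted p = 0.0620, 0.0799 and 0.113).

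Camera called mesenchyme, choroid plexus, signalling and neural crest lists higher in organoids labelled 53BP1 KO with the preset correlation only, with few or no members past the test. COL1A2 rose 4.82-fold (206 ± 56.9 against 42.9 ± 3.04, adjusted p = 0.0400), the 1 rise of 18 matrix genes, whose median was 1.66 (5 rises adjusted over the list alone, camera adjusted p = 7.08e-09, adjusted p = 0.11 with an estimated correlation). Outside the list the collagen receptor DDR2 (3.08-fold), the thrombospondin THBS1 (5.28-fold) and the junction gene PERP (5.54-fold) rose. Choroid plexus and cortical hem genes had a median of 3.79 and no call of 13 (4 rises adjusted over the list alone, camera adjusted p = 2.75e-06, adjusted p = 0.438 with an estimated correlation), MSX2 at 26.4 ± 15.7 against 1.7 ± 1.52 (adjusted p = 0.0890). The choroid plexus gene TTR was at 1783 and 1995 plain CPM in clone 3, 65.0 to 187 in clones 1 and 2 and 39.9 and 0.861 in the controls (adjusted p = 0.428). Targets of Wnt, BMP and TGF-beta signalling had a median of 1.33 and no call of 18 (7 rises and 1 fall adjusted over the list alone, camera adjusted p = 4.68e-06, adjusted p = 0.212 with an estimated correlation), LEF1 at 32.4 ± 8 against 9.83 ± 2.95 (adjusted p = 0.0550). Neural crest genes, with TWIST1 at 14.9 ± 8.32 against 0.862 ± 1.22, had no call of 14 (0 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.731 with an estimated correlation, 0.0623 without control 2). Counts over silent genes differed between these libraries: 4 of the 6 KO libraries had 3904 to 6716 plain CPM over them and the other 2 had 184 and 888, against 3608 and 91.5 in controls 1 and 2. Other lists leaned upward too, with 21 of 22 midbrain and hindbrain genes, 22 of 23 mesoderm and endoderm genes and 16 of 17 pluripotency genes above 0 on the log2 scale.

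**Figure D5:**
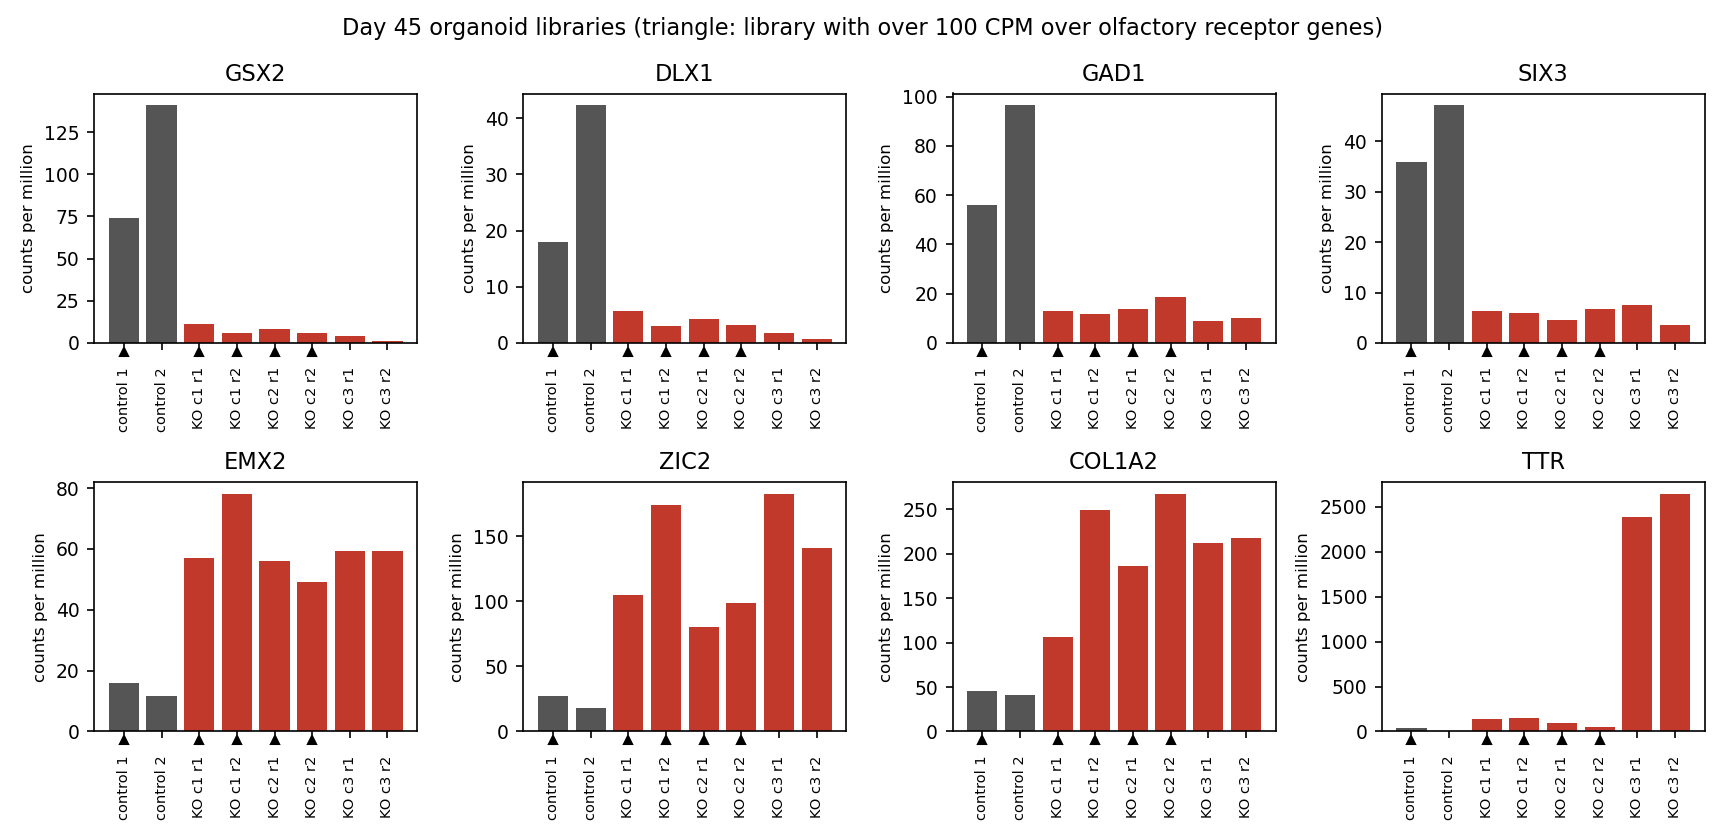
Normalized CPM of 8 genes in each of the 8 organoid libraries, controls in grey and 53BP1 KO in red. Triangles mark libraries with a high summed count over olfactory receptor genes (203 to 356 plain CPM, against 16.1 to 61.3 in the others).

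edgeR called 72 of 23706 genes in the organoids, 10 higher and 62 lower, and 70 of them at least 2-fold (13.9% higher), against 1114 with DESeq2 (49.0% higher). The count was 15, 22, 23, 35 and 40 without clone 1 replicate 1, clone 1 replicate 2, clone 2 replicate 1, clone 2 replicate 2 and clone 3 replicate 2, and 232 and 1 without control 1 and control 2. With libraries of a clone summed edgeR called 0 genes (1237 at unadjusted p below 0.05). Within the 5 libraries with a high olfactory receptor count 586 genes were called, and within the other 3 libraries 4382. Each subset holds 1 control library, the second only 1 clone, and both re-use the libraries behind the 72 calls, so these counts are no independent test of them. GSX2 changed by -3.32 and -5.61 on the log2 scale within these subsets, GAD1 by -1.97 and -3.41, EMX2 by 1.88 and 2.30, and SLC32A1 by -2.41 and -3.85, past the test only in the first. Mesoderm and endoderm genes (0 calls of 23; 0 adjusted over the list alone, camera adjusted p = 0.037, adjusted p = 0.825 with an estimated correlation) and H3K27 and H3K4 methylation genes (0 of 21; 0 adjusted over the list alone, camera adjusted p = 0.0396, adjusted p = 0.825 with an estimated correlation) were called by camera but pointed the other way without control 2 (0.579 each), and both calls were lost with RLE size factors (0.0622 and 0.0799).

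Across both differentiated systems 36 genes were called in the same direction in 53BP1 KO, 1 higher and 35 lower, of 17073 tested in both, against 9.27 for independent lists, and 3 were called in opposite directions. The shared falls included NRXN3 (log2 -2.31 in neurons and -2.33 in organoids), SIX3 (-2.09 and -2.84), ROBO2 (-2.07 and -1.51), KCTD16 (-1.96 and -1.87), CCSER1 (-2.17 and -1.44) and KIAA0408 (-1.77 and -1.10). The log2 changes correlated at 0.312 across genes. The shared count was 20, 0 and 49 without neuron clone 1 replicate 1, clone 1 replicate 2 and clone 2, 0 and 6 without neuron control 1 and 2, 8, 12, 14, 20, 55 and 24 without organoid clone 1 replicates 1 and 2, clone 2 replicates 1 and 2 and clone 3 replicates 1 and 2, and 83 and 1 without organoid control 1 and 2. With DESeq2 it was 492.

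The genes of wild-type neural induction were followed into the KO neurons and organoids, which share no library with the comparison that defined them. Of the genes higher in hNPC, 1446 were tested in neurons, and 728 fell and 19 rose in the KO (median log2 -1.38; camera p = 4.65e-35, with an estimated correlation 0.0840). Of 1951 genes lower in hNPC, 1003 rose and 56 fell (median log2 1.79; camera p = 3.66e-27, with an estimated correlation 0.0672). In organoids 28 of 1575 genes higher in hNPC fell and 2 rose (median -0.06; camera p = 5.45e-05, with an estimated correlation 0.0132, or 0.0981 for the 200 genes with the smallest p), and 3 of 2069 genes lower in hNPC rose and 2 fell (median 0.76; camera p = 7.12e-10, with an estimated correlation 0.271). The median over all genes tested in organoids was 0.16. The organoid libraries also differed in counts over silent genes, and what part these had in the organoid medians was not tested. Of all 41 list calls made with the preset correlation of 0.01 none held with an estimated correlation, and fry called 25 of the 41. The losses do not show that correlation between genes made the calls. The epithelial list in hNPC had an estimated correlation of 0.00223, below the preset 0.01, and still lost its call (camera adjusted p = 0.102).

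The effect of 53BP1 KO was also compared between stages. It differed between neurons and ES cells in 5122 of 18350 genes, 2785 higher and 2337 lower in neurons. The genes named were GRHL2 (log2 4.88 in neurons and -0.09 in ES cells, difference 4.90, adjusted p = 3.74e-05), the DNA-binding gene ARID3B (difference 2.31), FAM83F (3.30), RBPMS2 (3.71), PLEKHG6 (3.97) and SALL4 (3.45), which rose in neurons and fell in ES cells. Between organoids and neurons the effect differed in 619 of 26431 genes, 231 higher and 388 lower in organoids. EPCAM (log2 -0.72 in organoids and 2.84 in neurons), the junction gene F11R (0.21 and 2.72), the telomere gene TERF1 (-0.17 and 2.38), ZDHHC23 (-1.14 and 2.10) and SLC2A3 (-0.36 and 2.27) were higher in KO neurons but not in organoids labelled KO, and the laminin LAMC2 (0.54 and -3.12) was lower in KO neurons only, all with adjusted p = 0.00413 for the difference. The first count was 2531 without neuron control 1. The organoid count was 271, 207 and 2032 without neuron clone 1 replicate 1, clone 1 replicate 2 and clone 2, 8 and 267 without neuron control 1 and 2, and 54 without organoid control 2.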

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

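The label swap, UTX batch range and UTX depletion tests below were chosen only after the result was seen; the other tests were written down before.

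The first pattern is pluripotency transcripts in day 22 neurons labelled 53BP1 KO. A mix of undifferentiated cells with cells like the control neurons would make the share of 159 ES-cell-only genes and the share of 275 neuron-only genes add up to about 1, and they added up to 0.490 (interval 0.435 to 0.551), 0.502 (0.473 to 0.576) and 0.546 (0.503 to 0.587) over 2000 resamples. These sums lay below 1, but they cannot decide on a mix. The ES-cell-only genes had to be far lower in control neurons, which left out POU5F1 and NANOG, genes of the pattern itself. POU5F1 averaged 901 plain CPM in the KO neurons against 827 in ES cell controls, and NANOG 77.0 against 106. The intervals cover the choice of genes only. A swap of KO and control labels is argued against by TP53BP1, whose highest KO value was 0.308 of the lowest control value. ES cell libraries labelled as neurons are argued against by neuron-only genes at a median of 6.95, 11.2 and 25.4 times their level in ES cell 53BP1 KO. A mix with undifferentiated cells stays open. Cells in another state than either reference could also give this pattern, and that stays open too.

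The second pattern is the spread of the libraries labelled UTX KD along neural induction. UTX KD 1 had 590 genes at least 4-fold apart from the hNPC mean, against 0 for each hNPC library, but any count above 0 would have met that bound and the hNPC libraries may be technical replicates, so a mislabelled progenitor library stays open. A batch effect was not tested either, since the range of 1.35 in the median log2 change of genes higher in hNPC is the pattern itself. The extent of depletion might order the libraries, as KDM6A and that median ran in opposite order (rho -1 over 3 libraries), but 3 libraries cannot tell. KDM6A was also low in control hNPC, at 50.6 to 52.5 plain CPM. Its level therefore cannot separate depletion from a shift along neural induction. What set the libraries apart stays open.

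The third pattern is counts over silent genes in organoid libraries. Olfactory receptor genes (354) summed to 223, 347, 252 and 356 plain CPM in KO clones 1 and 2 and to 203 in control 1, against 16.1 and 61.3 in clone 3 and 26.96 in control 2. Genomic DNA was left undecided: counts and exonic length correlated across genes at 0.291 to 0.335 in these 5 libraries, but the check is void because only 40.1% of the 5089 genes had a length. Reads carried over from the other libraries are argued against by counts in control 1 for 72.9% of 2788 genes that had none in those libraries. The source of these counts stays open.

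The counts of calls were set against those from regrouped libraries. Only 1 of 56 splits, the real one, gave as many calls in ES cell 53BP1 KO (1935, highest other 731). The same held for 1 of 56 in UTX KD (2608, highest other 1) and 1 of 56 in hNPC (12265, highest other 1). This argues against chance only if the libraries are independent, which the labels do not say. The other splits mix both groups, so their low counts are not those of unchanged groups. Nor can a split tell the labelled difference from another one between the groups, such as RN7SL1 in UTX KD. The 731 came from controls 2, 3 and 4 set against the KO libraries with controls 1 and 5, so the controls also differed among themselves. Against controls 1 and 2 alone edgeR called 0 genes in 53BP1 KO (3219 at unadjusted p below 0.05), and 2514 against controls 3 to 5. The splits do not exclude that differences among the controls shape the 53BP1 KO count. For UTX KD against 53BP1 KO 1 of 10 splits gave as many calls (4286, highest other 3), too few splits to tell.

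The effect of 53BP1 KO differed between groups in 5122 genes for neurons against ES cells and in 619 for organoids against neurons. The differences on the log2 scale were 2.31 for ARID3B, 4.90 for GRHL2, 3.30 for FAM83F, 3.71 for RBPMS2, 3.97 for PLEKHG6 and 3.45 for SALL4 in the first, and -2.58 for TERF1, -2.53 for F11R, -3.26 for ZDHHC23, 3.62 for LAMC2, -2.65 for SLC2A3 and -3.61 for EPCAM in the second.

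Of 150 groups of values tested with Dixon's test, 18 held a library far from the rest. Chance gives about 1 in 20 for independent groups, but the same libraries recur over genes here, so no excess can be read from this. For CTSG, OTP and HOXB2 the other controls were all at 0, where Dixon's test flags any value above 0. Among ES cell controls these were, in CPM, control 1 for CTSG (0.0388, others 0), BCHE (9.16, others 2.75 to 4.13) and ROBO3 (13.1, others 6.12 to 7.87), and control 2 for CTSF (46.7, others 1.63 to 7.61), ASH2L (61.7, others 38.8 to 45.0), UTF1 (6.76, others 0.702 to 1.64), POU3F3 (1.01, others 0.0615 to 0.225), POU3F2 (7.13, others 0.261 to 1.87), HOXB2 (0.0371, others 0) and USP28 (182, others 131 to 142). Control 4 stood apart for OTP (0.0396, others 0), and control 5 for RPS19 (657, others 522 to 559), EBF1 (0.0615, others 0.311 to 0.383) and its gene counts (32.0M, others 25.0M to 26.8M). Among organoid KO libraries clone 1 replicate 2 stood apart for EMX2 (78.1, others 49.0 to 59.5) and ASCL1 (36.1, others 56.5 to 64.5), clone 3 replicate 1 for ELAVL3 (46.1, others 33.6 to 38.1) and clone 2 replicate 1 for BMP4 (4.86, others 8.43 to 9.64).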

How the results depend on the processing

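Chosen only after the results were seen were the fits of single UTX KD libraries, the organoid background settings, disjoint controls, fry on the neural induction genes, the sets of 200 genes with an estimated correlation, and leaving out libraries and calls of at least 2-fold in the contrasts of effects. The organoid libraries were the shallowest, at 3.15M to 20.9M counts, which limits calls for genes of few counts. In the neuron and organoid comparisons 1 library decided the count. In ES cell 53BP1 KO, DESeq2 called 3050 genes, 227 passed with at least 2-fold change, and leaving out 1 library gave 391 to 3112. No paired analysis was possible because all KO libraries carry replicate number 1. In UTX KD, DESeq2 called 4534, 1205 passed with at least 2-fold change, the joint fit with hNPC called 6075, UTX KD 1 alone 7077 and UTX KD 2 alone 911 (fits where the KD group has no spread of its own), and leaving out 1 library gave 629 to 5317. EBF3 and EBF1 reversed with UTX KD 2 alone (log2 -0.00398 and -1.01). In hNPC 7143 passed with at least 2-fold change. In neurons summed clones gave 1535 and leaving out 1 library 0 to 7476. In organoids DESeq2 called 1114, summed clones gave 0, the olfactory receptor covariate 862, the 5 libraries with high background 586 and the 3 with low background 4382 (1 control library each), and leaving out 1 library gave 1 to 232. Fewer libraries and clones enter the summed fits. The cause of the other moves was not tested.

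With the replicate number as a block UTX KD gave 0 calls (3293 at unadjusted p below 0.05), hNPC 11193, neurons 2209 and organoids 12. Correlations between libraries of the same number ranged from -0.155 to -0.0333 in UTX KD, from -0.0377 to 0.0236 in hNPC and from -0.630 to -0.295 in organoids, and stood at 0.0897 in neurons. Libraries of the same number thus did not vary together beyond 0.0897. In organoids those of different numbers did (0.295 to 0.630), a mirror image that 2 controls force, so the libraries shared a structure that the numbers do not name. The block also costs degrees of freedom, and what lowered the counts was not tested.

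Of the genes that differed between UTX KD and 53BP1 KO 2068 passed with at least 2-fold change. Leaving out 1 library gave 1931 to 6551 genes there, 2531 to 6386 between neurons and ES cells, and 8 to 2032 between organoids and neurons. The ES cell overlap was 560 with DESeq2, 49 with at least 2-fold change in both, 0 and 0 with disjoint controls (void, since edgeR called 0 genes in 1 comparison of each arrangement, with 3219 and 1824 at unadjusted p below 0.05), 512 with UTX KD 1 alone, 65 with UTX KD 2 alone and 47 to 443 without 1 library. The overlap of neurons and organoids was 492 with DESeq2 and 0 to 83 without 1 library. The cause was not tested.

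Of 41 gene list calls 0 held with an estimated correlation and 39 held with RLE size factors. The lowest camera adjusted p with an estimated correlation was 0.102, for a list whose estimated correlation (0.00223) was below the preset one. The loss of that list therefore cannot be put down to a correlation above the preset one. Other called lists had far higher estimates, such as 0.906 for ribosomal protein genes in UTX KD and 0.813 in neurons. For those lists correlation between genes stays open. Of 280 fits of called lists without 1 library 264 kept the call, 14 lost it and 2 reversed direction: the mesoderm and endoderm list in organoids had adjusted p of 0.0031 to 0.579 and the H3K27 and H3K4 methylation list 0.00403 to 0.579, both reversed without organoid control 2. The cause was not tested. Neural induction genes lost their call with an estimated correlation in neurons (0.0840 for genes higher and 0.0672 for genes lower in hNPC) and, for genes lower in hNPC, in organoids (0.271, and 0.231 with fry), and genes higher in hNPC kept it in organoids (0.0132). The other fry p-values were 0.0113 for genes higher and 0.00890 for genes lower in hNPC in neurons, and 0.00843 for genes higher in hNPC in organoids. The sets of 200 genes were called with the preset correlation (2.36e-23, 1.24e-39, 8.53e-08 and 7.09e-07) and not with an estimated one (0.154 and 0.0770 in neurons, 0.0981 and 0.158 in organoids, for genes higher and lower in hNPC). The cause was not tested. Named genes kept their status, called or uncalled, in 110 of 128 results of other settings and 187 of 256 of fits without 1 library in ES cell 53BP1 KO, 162 of 207 and 225 of 335 in UTX KD, 234 of 235 and 376 of 376 in hNPC, 319 of 340 and 181 of 339 in neurons, and 180 of 252 and 245 of 336 in organoids. In the main fits 29 of 32, 37 of 42, 47 of 47, 68 of 68 and 21 of 42 named genes were called, in that order. Uncalled genes that stayed uncalled count as kept, so these are not numbers of calls that held. The organoid fit with summed clones called 0 genes and still counts 21 of 42 as kept.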

Other observations

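CTSG, SRGN and LYZ, which encode proteins of myeloid granules, were also read beyond the ES cell 53BP1 KO libraries. SRGN was at 6.99, 0.0409 and 6.69 plain CPM in UTX KD 1, 2 and 3, against 3.06 to 3.69 in ES cell 53BP1 KO and 0 to 0.232 in ES cell controls. LYZ was at 4.88, 0.0409 and 27.6 in UTX KD and CTSG at 0.674, 0 and 0.349. In neurons CTSG, SRGN and LYZ stayed at 0.369 or less in every library. In organoid KO clones 1 and 2 LYZ reached 2.78, CTSG 1.83 and SRGN 1.78 plain CPM, against at most 0.897, 0.326 and 0.653 in the controls and 0.303 or less in clone 3. Clones 1 and 2 also had high counts over silent genes. The list of blood, endothelium and microglia genes passed camera in no comparison (adjusted p = 0.27 in ES cell 53BP1 KO, 0.972 in UTX KD, 0.783 in hNPC, 0.894 in neurons and 0.066 in organoids).

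Targets of p53 were lower in 3 of 20 cases in ES cell 53BP1 KO (3 adjusted over the list alone, camera adjusted p = 0.0579, 0.787 with an estimated correlation), with none called in UTX KD or organoids and 6 falls and 2 rises in neurons (6 and 3 adjusted over the list alone, camera adjusted p = 0.171). Glial genes had 3 falls and 1 rise of 14 in neurons (4 and 1 adjusted over the list alone, camera adjusted p = 0.178) and none in organoids (2 rises adjusted over the list alone, camera adjusted p = 0.444). Immediate early genes fell in 5 of 18 cases and rose in 1 in neurons (7 and 2 adjusted over the list alone, camera adjusted p = 0.21). The RNA of ribonuclease MRP, RMRP, was at 11959 to 15478 plain CPM in ES cell 53BP1 KO against 5639 to 8796 in ES cell controls.

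Of gene counts, RN7SL1 held 14.9 to 27.1% in organoid 53BP1 KO, 13.6 to 20.9% in organoid control, 4.86 to 5.61% in neuron 53BP1 KO and 6.48 to 6.77% in neuron control.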
